A study of Mus musculus with 54 samples.

How the data were processed

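Single-cell RNA sequencing of lymphocytes sorted from mouse lung was analysed. The 10 libraries came from female C57BL/6 wild-type mice, with 1 library of innate lymphoid cells (ILCs; lineage-negative, CD3-negative, TCRβ-negative, Thy1-positive) and 1 library of CD4 T cells (CD3-positive, TCRβ-positive, CD4-positive) at each of 5 times. The times were steady state and days 2, 5, 9 and 14 after infection with Nippostrongylus brasiliensis, a helminth whose larvae pass through the lung. The labels give a 10x Chromium Single Cell 3-prime version 2 library and no sequencing batch. Of the 54 samples in the labels, the 14 chromatin accessibility samples and the 30 other RNA samples were not analysed here.

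The authors processed the libraries with Cell Ranger, of which no version is given, against genome build mm10. The deposited values are UMI counts (a UMI is a tag that marks 1 captured RNA molecule) per gene and cell barcode, without normalization. The values were checked to be whole numbers, and the 27998 genes had the same identifiers in all 10 libraries. Droplets without a cell were not used here, so no background profile was subtracted.

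Total UMIs per library ran from 877180 in the day 5 CD4 T library, which held 254 barcodes, to 26261024 in the day 5 ILC library. Cells were kept with at least 300 genes, at most 10% of UMIs from mitochondrial genes and no doublet call by Scrublet as built into scanpy (expected rate 0.06, seed 0). Scrublet called 163 doublets in all and none in 6 of the libraries, so doublets were largely left in. Of 32808 barcodes, 31184 cells were kept, 15881 in the ILC and 15303 in the CD4 T libraries. More than 10% mitochondrial UMIs was found in 12.4% of barcodes of the steady-state ILC library, 13.2% of the day 9 ILC library and 12.0% of the day 9 CD4 T library, against 0.270% to 5.91% elsewhere.

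ILC and CD4 T libraries were clustered apart, without batch correction. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes gave 30 principal components, and 15 neighbours gave Leiden clusters at resolution 0.8. Antigen receptor, ribosomal and mitochondrial genes and the lists of neuropeptides, type 2 effectors and the cell cycle were kept out of the variable genes. The members of the first 2 of these lists are called left-out genes, and they could be compared between clusters without having formed them. This gave 20 ILC and 13 CD4 T clusters. Each cluster was named from markers of 23 cell classes fixed before the data were examined. The ILC and T cell classes open to a cluster depended on its compartment. ILC clusters could be named ILC2, ILC3, NK or ILC1, or T cell. CD4 T clusters could be named naive, regulatory, Th1 or cytotoxic, Th2, Th17 or follicular helper T. The names ILC2 and Th2 were thus never weighed against each other. ILC clusters were set against the median cluster of both compartments, CD4 T clusters against that of their own. The name went to the open class with the highest mean log2 excess over that median. That class also needed the largest share of its markers up by 1.5-fold, at least 3 such markers, and more of its markers among the cluster's 10 leading genes than any other class. The last condition was relaxed after the data were examined. A cluster with no marker of any class among its leading genes also took its best class when its median UMI count was at least 0.333 of its libraries' median. Clusters that missed any of these conditions were left unnamed. They held 3.21%, 2.23%, 28.1%, 14.5% and 6.78% of ILC-library cells and 4.94%, 10.6%, 8.04%, 11.4% and 9.05% of CD4 T cells at steady state and days 2, 5, 9 and 14. The word like after a class name means that the class was inferred from RNA.

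UMI counts were summed over the cells of a library, or over a class within a library. Sums were compared with edgeR's quasi-likelihood test (glmQLFit, glmQLFTest) after TMM normalization and filterByExpr, with Benjamini-Hochberg adjustment at 0.05. The model held day as a block plus the compartment or class, over 10 sums with 4 residual degrees of freedom. The SE beside a log2 fold change is the absolute log2 fold change divided by the square root of the test's F statistic. It is not a spread over days. Days are not replicates of 1 condition, so these tests ask whether a difference held over the 5 times. It was set against the gene's variation between times after moderation toward a trend over all genes. The moderation adds degrees of freedom borrowed from all genes. A p-value can thus be far smaller than 5 days alone would give. A gene that varied more between days than others of its level can thus still pass. The comparisons were ILC against CD4 T libraries, ILC2-like against the other cells of the ILC libraries (read for left-out genes alone), and ILC2-like against Th2-like cells (each sum with at least 20 cells). The 4 residual degrees of freedom are few, and libraries from the same mice cannot be told from the labels.

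No test was possible between days, since each day had 1 library per compartment. Levels are given as counts per 1e6 UMIs (CPM) of the summed counts with exact Poisson 95% intervals. Ratios between days are given on the log2 scale after adding 5 CPM, and a gene was called higher or lower at 1.5-fold or more when the exact conditional (Clopper-Pearson) 95% interval of the raw ratio excluded 1. Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals. All these intervals cover counting error only, not variation between mice or libraries. Cells were also thinned to 1 number of UMIs, 700 for ILC2-like and 600 for CD4 T cells, before shares with a UMI were compared. The median log2 ratio of each list was set beside 10000 random lists of the same size drawn within 20 expression bins. A percentile from this draw is descriptive, since the genes of a list are not independent.

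The 15 gene lists were fixed before the data were examined: neuropeptides and their receptors, type 2 cytokines and effectors, alarmin receptors and ILC2 identity, cAMP and PKA response, early response and dissociation stress, cell cycle, checkpoints and negative regulators, trafficking and residency, glycolysis, lipid handling, interferon response, regulatory T cell genes, cytotoxic and type 1 genes, type 3 genes, and antigen receptor and CD3 genes (the sort gate). Some genes stand on more than 1 list, such as Il2ra, Ctla4 and Cxcr3. Genes named in the text were also chosen by a rule fixed then. Detected members of the neuropeptide and type 2 effector lists are named, except 1 that is counted with its list but not reported here. In the tested comparisons, the 10 genes each way with the largest log2 fold change were named among those past the threshold with 1 direction on all 5 days. Between days, among genes with at least 50 UMIs in both sums together and 30 CPM in the higher one, 10 each way were named for ILC2-like cells at day 5 and CD4 T cells at day 9, and 5 each way for the other days. Single genes given as examples beside the counts of the other lists were chosen after their values were seen. Unnamed gene models, ribosomal and mitochondrial genes, antigen receptor segments, haemoglobins and sex-linked markers were passed over. For a gene with 0 UMIs in 1 group, the fold is a lower bound against 3 counts over that group. For a gene with 1 to 3 UMIs, the raw ratio is given with its exact conditional 95% interval.

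Alternatives fixed before the data were examined were DESeq2 size factors within edgeR, the DESeq2 Wald test, limma-voom, no filter on low counts, no block, each day's pair of sums left out in turn, and libraries subsampled to the cell number of the smallest. Others changed cell filters (doublet calls kept, 5% mitochondrial limit, at least 500 genes), clustering (resolution 0.4 or 1.2, all variable genes), scaling by TMM, the pseudocount (1 or 20 CPM) and depth per cell (thinning). Added after the data were examined were the removal of the cells with the top doublet scores, ILC libraries without endothelial, stromal and B cells, 3 ILC clusters (numbers 5, 11 and 12) moved into the ILC2-like class or left out, and 1 cluster (number 10) taken out of the Th2-like class.

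The tests were tried on simulated data with 200 changed genes. At a 2-fold change, 70.1%, 36.1% and 69.4% of changed genes were found in the 3 comparisons, and at a 4-fold change 92%, 91% and 93%. Each simulated gene had the trend variation of its level and no change between days. The rates of these 3 comparisons therefore do not hold for genes that vary more than the trend, such as Calca. Between 2 simulated days, 69% of 2-fold and 91% of 4-fold changes were called in the right direction. Those 2 days were drawn with counting error alone, without variation between libraries, mice or cells. Their rates therefore do not give the error of calls between real libraries. Unchanged genes called were 9, 4 and 4 in the 3 comparisons and 28 between the 2 days. Coordinates of 130 of 133 named genes came from the RefSeq annotation of GRCm38, the assembly that mm10 is built on, matched by symbol. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.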

Results

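RNA of single lung lymphocytes was counted in 10 libraries, 1 of sorted ILCs and 1 of sorted CD4 T cells at steady state and at days 2, 5, 9 and 14 of infection with the helminth Nippostrongylus brasiliensis. ILCs are lymphocytes without antigen receptors, and those of group 2 (ILC2s) make the same type 2 cytokines as Th2 cells, the CD4 T cells of anti-helminth immunity. The series title concerns the neuropeptide CGRP, encoded by Calca, and ILC2s. From steady state to day 14 in the order given, the ILC libraries held 5263944, 12565458, 26261024, 10446227 and 11596205 UMIs, and 2464, 2824, 3714, 2662 and 4217 cells were kept. The CD4 T libraries held 11183732, 10848584, 877180, 10840903 and 10820677 UMIs, and 5567, 2838, 224, 3602 and 3072 cells were kept. Median UMIs per kept cell were lowest in both steady-state libraries, 1655.5 in ILCs and 1628 in CD4 T cells. They lay between 2342 and 5550 in the other ILC libraries and between 2703.5 and 3617.5 in the other CD4 T libraries. Each group had 1 library, so no value below has a replicate of its own group.

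ILC2-like cells were the largest class of the ILC libraries at each time, and Th2-like cells became common in the CD4 T libraries late in infection. ILC2-like cells were 58.3% of kept ILC-library cells at steady state (95% Clopper-Pearson interval 56.3 to 60.3), 79.2% at day 2, 51.5% at day 5, 82.8% at day 9 (81.3 to 84.2) and 86.2% at day 14. Th2-like cells were 1.54% of kept CD4 T cells at steady state, 2.96% at day 2, 16.5% at day 5 (11.9 to 22.0, 37 of 224 cells), 31.0% at day 9 (29.4 to 32.5) and 37.4% at day 14 (35.7 to 39.1). Naive-like cells were 83.6% of CD4 T cells at steady state, 42.6% at day 9 and 44.4% at day 14.

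The steady-state ILC library was 33.8% endothelial-like cells (32.0 to 35.8), which the gate was not meant to hold. This share was 8.39% at day 2 and between 0.639% and 3.10% later. Stromal-like cells were 0.263% to 2.37% of the ILC libraries, and NK or ILC1-like cells 1.62% to 7.75%. At day 5, 12.0% of ILC-library cells were in the cycling cluster and 28.1% in unnamed clusters. Of the 917 cells of the largest unnamed ILC cluster, 879 came from day 5. Regulatory T-like cells were 3.38% to 6.70% of the CD4 T libraries, Th1-like or cytotoxic cells at most 5.03%, Th17-like cells 0.539% to 1.28%, cycling cells 0.282% to 4.02%, and interferon-responding cells 0.586% to 7.51%, highest at day 2.

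The ILC2-like share depended on the clustering. At day 9 it ran from 42.2% to 95.5% over 8 alternative settings, and at day 5 from 48.5% to 87.7%, as cells moved between this class and unnamed or cycling clusters. The Th2-like share ran from 25.3% to 31.0% at day 9, from 35.1% to 38.2% at day 14 and from 2.30% to 19.2% at day 5, the smallest library. Over alternatives, regulatory T-like cells reached 16.1% at day 2 and 18.4% at day 9, and Th1-like or cytotoxic cells 17.0% at day 5 and 15.8% at day 9. Interferon-responding cells ran from 0.428% to 8.81% at day 2. Cycling CD4 T cells ran from 0.056% to 3.35% at day 9, and Th2-like cells from 0.808% to 1.58% at steady state. The Th2-like class held different clusters over time. Cluster 10, with the lowest Th2 marker score of its 3 clusters, held 62 of 84 Th2-like cells at day 2 and 34 of 37 at day 5, cluster 5 held 916 of 1115 at day 9, and cluster 6 held 760 of 1148 at day 14. These shares describe single libraries and were not tested.

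**Figure D1:**
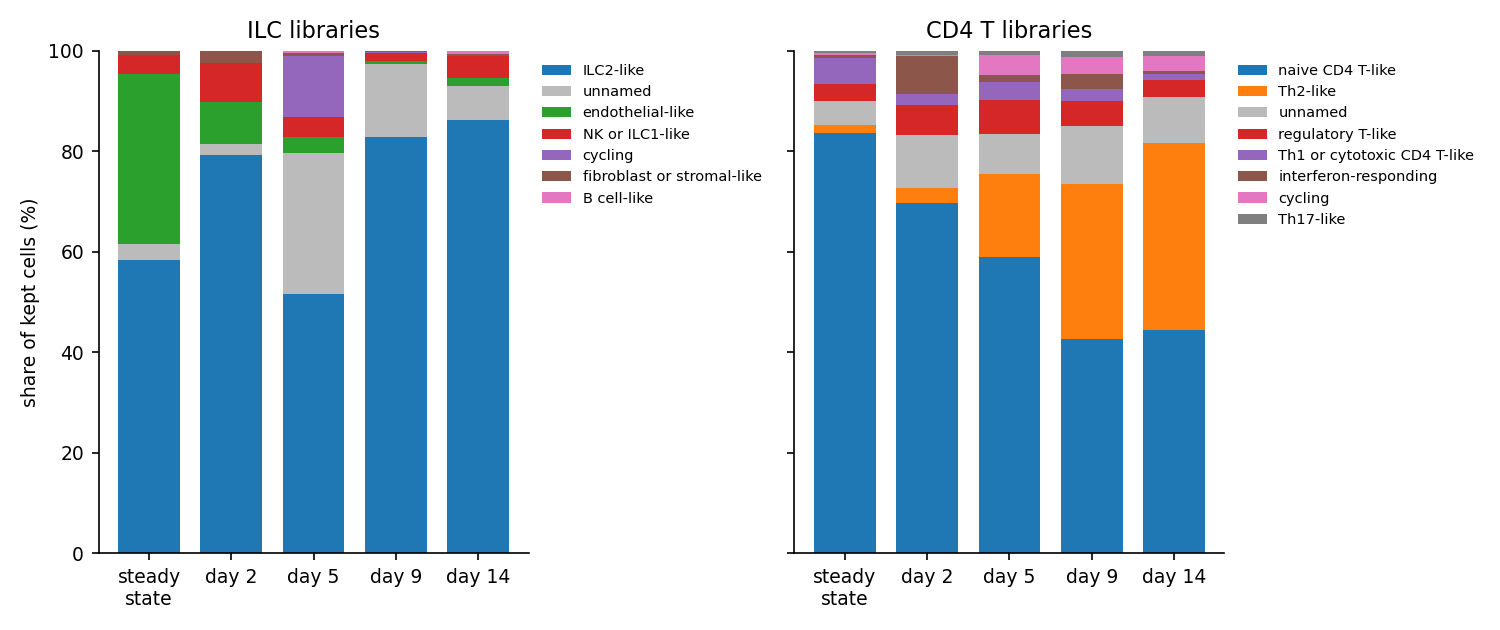
Share of kept cells (%) in each inferred class, by time, in the 5 ILC libraries (left) and the 5 CD4 T libraries (right), with 1 library per bar. Th2-like cells were 1.54% of CD4 T cells at steady state and 37.4% at day 14, and endothelial-like cells were 33.8% of the steady-state ILC library.

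The comparison of whole ILC with whole CD4 T libraries asked which genes separated the 2 kinds of library at all 5 times. It was not adjusted for cell make-up, and naive-like cells were 42.6% to 83.6% of the CD4 T libraries. ILC libraries held more RNA of type 2 effectors and of CGRP receptor genes. Arg1, which encodes arginase-1, was higher in ILCs by 8.24 ± 0.48 log2 units (± SE, n = 5 days, higher on 5 of 5 days, adjusted p = 6.92e-06), at 514 ± 273 CPM (SD) against 2.95 ± 3.41. Ramp1, whose product forms the CGRP receptor together with that of Calcrl, was higher by 3.23 ± 0.24 (5 of 5 days, adjusted p = 2.18e-05), at 468 ± 117 against 49.1 ± 12.8 CPM. Calca was higher by 4.10 ± 1.39 (5 of 5 days, adjusted p = 0.0382), at 2350 ± 3610 against 101 ± 106 CPM. Ramp3, which pairs with Calcrl in an adrenomedullin receptor, did not pass the test, with a log2 fold change of 0.29 ± 0.23. Calca lies on chromosome 7 at 114625981 to 114636910, Ramp1 on chromosome 1 at 91179822 to 91225196 and Ramp3 on chromosome 11 at 6658506 to 6677478 (GRCm38).

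Of 13 tested genes of the neuropeptide list, 11 were higher in ILCs and 1 lower (adjusted over the list alone, 11 and 1). Among the higher genes were Calca, Calcb, Calcrl, Ramp1, Ramp2, Adm, Nmur1, Vipr2, Penk and Adora2a. Vipr1 was lower, at 0.133 against 8.22 CPM, while Vipr2, the other receptor for vasoactive intestinal peptide, was higher by 6.48 ± 0.41. Ramp2 had 1946 UMIs in ILC and 2 in CD4 T libraries, a ratio of 665 (95% interval 184 to 5500). Of the ILC UMIs of Ramp2, 1900 lay outside the ILC2-like cells. For Calcrl the number was 626 of 1793 and for Adm 450 of 1563. Mean Calcrl was 53.5 CPM in those other cells and 28.8 in ILC2-like cells, and mean Adm 37.9 and 24.2. Nmur1, the neuromedin U receptor gene, was near the detection limit with 73 UMIs in ILC libraries and 1 in CD4 T libraries, a ratio of 49.9 (8.68 to 2000). Of the 16 type 2 effector genes, 14 were higher in ILCs and 0 lower (adjusted over the list alone, 15 and 1). Il5 was higher by 6.70 ± 0.96, Il13 by 6.14 ± 0.82, Csf2 by 6.55 ± 0.76 and Areg by 5.28 ± 0.58. Ccl1, Lif, Hbegf, Il6, Tnf, Il2, Il4 and Tnfsf11 were also higher, by 1.10 to 5.78. Il9 had 5365 UMIs in ILCs and 2 in CD4 T cells, a ratio of 1830 (507 to 15100), but 4646 of the ILC UMIs came from 2 cells of the day 5 library. Il10 and Il3 did not pass the test at -2.15 and 2.16.

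By the ranking rule, the 10 genes named as higher in ILCs had 0 UMIs in CD4 T libraries, and 8 of them lay mainly in endothelial-like, stromal-like or B-like cells. Lcn2 was at least 750-fold higher, Nts (neurotensin) 567-fold, Plvap 358-fold, Gpm6a 280-fold, Fbln5 269-fold, Galnt18 197-fold, Pgf 178-fold and Sash1 174-fold. From 86.0% to 99.1% of the ILC UMIs of these 8 were there. Bmp2 (at least 441-fold) and Rgs18 (at least 324-fold) differed, with 4.60% and 1.90% of UMIs in those cells. Higher in CD4 T cells were Cd4, part of the sort gate (log2 fold change -6.95), and the T cell genes Cd5 (-7.30) and Cd6 (-6.80), with Dapl1 (-8.67), Slfn1 (-7.11) and Izumo1r (-6.81), the folate receptor 4 gene of regulatory T cells. Galnt9, Gzmk, Ifit1bl1 and Chil5 had 1 to 3 UMIs in ILCs, and their CD4 T levels stood at ratios of 430 (76.6 to 17000), 88.2 (29.7 to 432), 180 (31.7 to 7160) and 84.8 (23.0 to 709).

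Alarmin receptor and ILC2 identity genes were mostly higher in ILCs, with 13 of 19 tested higher and 2 lower (adjusted over the list alone, 13 and 2). Examples were Klrg1 (4.62 ± 0.36) and the IL-33 receptor gene Il1rl1 (3.89 ± 0.81). Type 3 genes were higher in 7 of 10 and lower in 0 (list alone 7 and 0), including Il17a at 3.57 ± 0.41. Here and below, list alone stands for adjusted over the list alone. Of the cAMP response genes, 9 of 14 were higher and 2 lower (list alone 11 and 2), led by Nr4a3 at 1.81 ± 0.27. Early response and dissociation stress genes, which tissue digestion also induces, were higher in 11 of 19 and lower in 2 (list alone 11 and 2), with Fos at 2.26 ± 0.24. Lipid handling genes were higher in 8 of 14 (list alone 8), checkpoint genes in 8 and lower in 2 of 14 (list alone 8 and 2), and glycolysis genes higher in 5 of 14 (list alone 5). The 8 lipid genes included Fabp4 and Cd36, known genes of endothelium, at 7.91 ± 0.87 and 5.34 ± 0.72, and endothelial-like cells were up to 33.8% of an ILC library. Pdcd1 of the checkpoint list was higher by 2.46 ± 0.31. Interferon response genes were lower in ILCs in 10 of 14 and higher in 1 (list alone 10 and 1), with Ifit3 at -2.14 ± 0.34. CD3 and other sort-gate genes were lower in 8 of 9, and Thy1, part of the ILC gate, was higher (list alone 8 and 1). Trafficking genes went both ways, 7 higher and 5 lower of 16 (list alone 9 and 5), with Itgae at 2.11 ± 0.39 and Ccr7 at -3.33 ± 0.21. Regulatory T cell genes split 5 to 4 of 12 (list alone 6 and 4), cytotoxic and type 1 genes 2 to 4 of 14 (list alone 2 and 4), and cell cycle genes 1 to 1 of 20 (list alone 0 and 0).

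Of 12444 genes tested with edgeR's quasi-likelihood test, 3655 were higher in ILC and 2215 in CD4 T libraries after Benjamini-Hochberg adjustment. Subsampling each library to 224 cells gave 1414 and 1016 genes, and leaving out the day 2 pair lowered the count higher in ILC to 2432. Without the steady-state or the day 5 pair, Calca missed the threshold (adjusted p = 0.0875 and 0.0859; range over 16 alternatives 0.00312 to 0.0875), as did Il4 (0.0651 and 0.0553, 0.0899 without day 2, 0.0602 with limma-voom and 0.329 without the block; range 0.0039 to 0.329). Calcb missed it without the steady-state (0.06) or day 2 pair (0.119) and with the DESeq2 Wald test (0.0504; range 0.0136 to 0.119). Adora2a and Tnfsf11 missed it without the day 2 pair (0.0952 and 0.101) and without the block (0.0614 and 0.412; ranges 0.00454 to 0.0952 and 0.00208 to 0.412), while Il10 passed without day 5 (0.00205; range 0.00205 to 0.541) and Il3 without day 9 (0.0348; range 0.011 to 0.241), and both passed with the DESeq2 Wald test (0.00762 and 0.011) and with no filter on low counts (0.0456 and 0.0497). Penk missed it without the block (0.0668) and after subsampling (0.317; range 0.000114 to 0.317).

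Within the ILC libraries, the question was which neuropeptide and type 2 genes distinguished ILC2-like cells from the other cells. Calca, Ramp1 and Ramp3 were higher in ILC2-like cells. Calca was higher by 2.35 ± 0.47 log2 units (± SE, n = 5 days, 5 of 5 days, adjusted p = 0.0119), at 2850 ± 4130 against 670 ± 899 CPM (SD). Ramp1 was higher by 1.76 ± 0.39 (5 of 5 days, adjusted p = 0.0168) and Ramp3 by 1.76 ± 0.30 (5 of 5 days, adjusted p = 0.00562). Il5 was higher by 2.32 ± 0.56 (5 of 5 days, adjusted p = 0.0234), at 2000 ± 966 against 568 ± 276 CPM, whereas Il13 did not pass (1.89 ± 0.72, adjusted p = 0.0939). The other cells were mostly endothelial-like at steady state (834 cells). At day 5 they included 879 cells of cluster 5 and 446 of cluster 12, and at day 9 303 of cluster 11. Il13 in these clusters stood near its ILC2-like level, as given under the last heading. The Il13 result thus does not set ILC2-like cells against clearly different classes alone. Without clusters 5, 11 and 12, 19 left-out genes were higher and 3 lower.

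Of 12 tested genes of the neuropeptide list, Calca, Ramp1, Ramp3, Vipr2, Penk and Adora2a were higher in ILC2-like cells, and Ramp2 and Tac1 were lower. Adjusted over the list alone the counts were also 6 and 2. Ramp2 stood at 1.33 against 167 CPM in the other cells, among them endothelial-like cells, in which it is known to be expressed. Tac1, the substance P gene, had 0 UMIs in ILC2-like and 26 in other cells, at least 15-fold lower. Calcrl, Calcb and Adm did not pass the test, at 0.16, 0.35 and 0.36. Of the 16 type 2 effector genes, 11 were higher and 0 lower (adjusted over the list alone, 12 and 0). They were Il5, Il9, Il2, Il3, Csf2, Areg, Arg1, Ccl1, Lif, Tnfsf11 and Tnf. Ccl1 was higher by 2.92 ± 0.50, Csf2 by 2.69 ± 0.48, Arg1 by 2.09 ± 0.42 and Areg by 2.05 ± 0.48. Il4, Il6, Il10 and Hbegf did not pass, at 0.94, -0.80, -1.28 and 0.11.

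In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 11912 genes, 17 of 28 left-out genes were higher and 2 lower. The count of 17 fell to 10 without the day 2 pair, and the count of 2 to 1 without the day 2, day 5 or day 14 pair. Adjusted p of Calca was 0.0597, of Ramp1 0.0689, of Il5 0.0988, of Areg 0.0945, of Arg1 0.0518, of Adora2a 0.0844 and of Tnfsf11 0.0529 without the day 2 pair. Without the day 5 pair, Il5 (0.0747), Areg (0.0700) and Adora2a (0.0567) missed the threshold. Over 19 alternatives the ranges were 2.33e-06 to 0.126 for Calca, 0.000117 to 0.0794 for Ramp1, 5.41e-05 to 0.184 for Il5, 6.67e-05 to 0.168 for Areg, 5.93e-06 to 0.127 for Arg1, 0.00170 to 0.0844 for Adora2a and 1.39e-05 to 0.136 for Tnfsf11. Penk and Il9 missed the threshold in 6 of 19 alternatives (ranges 1.41e-07 to 0.812 and 1.59e-24 to 0.746), with Penk at 0.25 log2 units for cells with at least 500 genes. Ramp3 missed it in 2 (3.14e-07 to 0.0647) and Tnf in 1 (1.24e-08 to 0.129), while Il13 passed in 6 (0.000131 to 0.648).

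ILC2-like and Th2-like cells, the innate and the adaptive type 2 cells, were compared next. ILC2-like cells held more RNA of 12 of 16 type 2 effectors and of Ramp1, while Ramp3 and Il4 did not pass the test. Arg1 was higher in ILC2-like cells by 7.0 ± 0.38 log2 units (± SE, n = 5 days, 5 of 5 days, adjusted p = 9.52e-19). Il5 was higher by 4.13 ± 0.33 (5 of 5 days, adjusted p = 2.03e-13), at 2000 ± 966 against 146 ± 120 CPM (SD), and Il13 by 3.50 ± 0.29 (5 of 5 days, adjusted p = 3.40e-13). Ramp1 was higher by 3.25 ± 0.22 (5 of 5 days, adjusted p = 6.65e-16), at 593 ± 82.9 against 84.5 ± 45.7 CPM. Calca was higher by 2.02 ± 0.52 (5 of 5 days, adjusted p = 0.00291), at 2850 ± 4130 against 410 ± 260 CPM. This difference was uneven over days. Over days 9 and 14, Th2-like Calca stood at 74.1% of its ILC2-like level. At day 2 it stood at 10210 CPM in ILC2-like cells, and none of the 84 Th2-like cells had a Calca UMI. Il10, an anti-inflammatory cytokine gene, was lower in ILC2-like cells by -3.88 ± 0.32 (lower on 5 of 5 days, adjusted p = 5.90e-13). Of the 466 Il10 UMIs of the ILC libraries, 410 lay outside the ILC2-like class. At day 5, Il10 stood higher in ILC clusters 5 and 12 than in ILC2-like cells, as given under the last heading. The Il10 result thus holds for the class as named.

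Of 10 tested genes of the neuropeptide list, 7 were higher in ILC2-like cells and 1 lower (adjusted over the list alone, 7 and 1). Besides Calca and Ramp1 these included Calcrl (1.28 ± 0.23), Adm (2.56 ± 0.39), Vipr2 (5.51 ± 0.40) and Penk (1.33 ± 0.26), and Vipr1 was lower with 4 against 39 UMIs. Ramp3 and Adora2a did not pass, at 0.33 ± 0.24 and 0.11 ± 0.22. Ramp3 was higher in ILC2-like cells on 2 of 5 days, and over days 9 and 14 its Th2-like level was 163% of the ILC2-like level. Of the 16 type 2 effectors, 12 were higher and 1 lower (adjusted over the list alone, 12 and 2). Areg, Csf2, Ccl1, Lif, Hbegf, Tnf, Il6 and Il2 were higher by 1.99 to 3.91. Il4, Il3 and Tnfsf11 did not pass, at -0.07, -0.09 and -0.44. Tnfsf11 passed without the day 2 pair (adjusted p = 0.0325) and without the day 5 pair (0.0175), with a range over 19 alternatives of 8.92e-05 to 0.461.

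**Figure D2:**
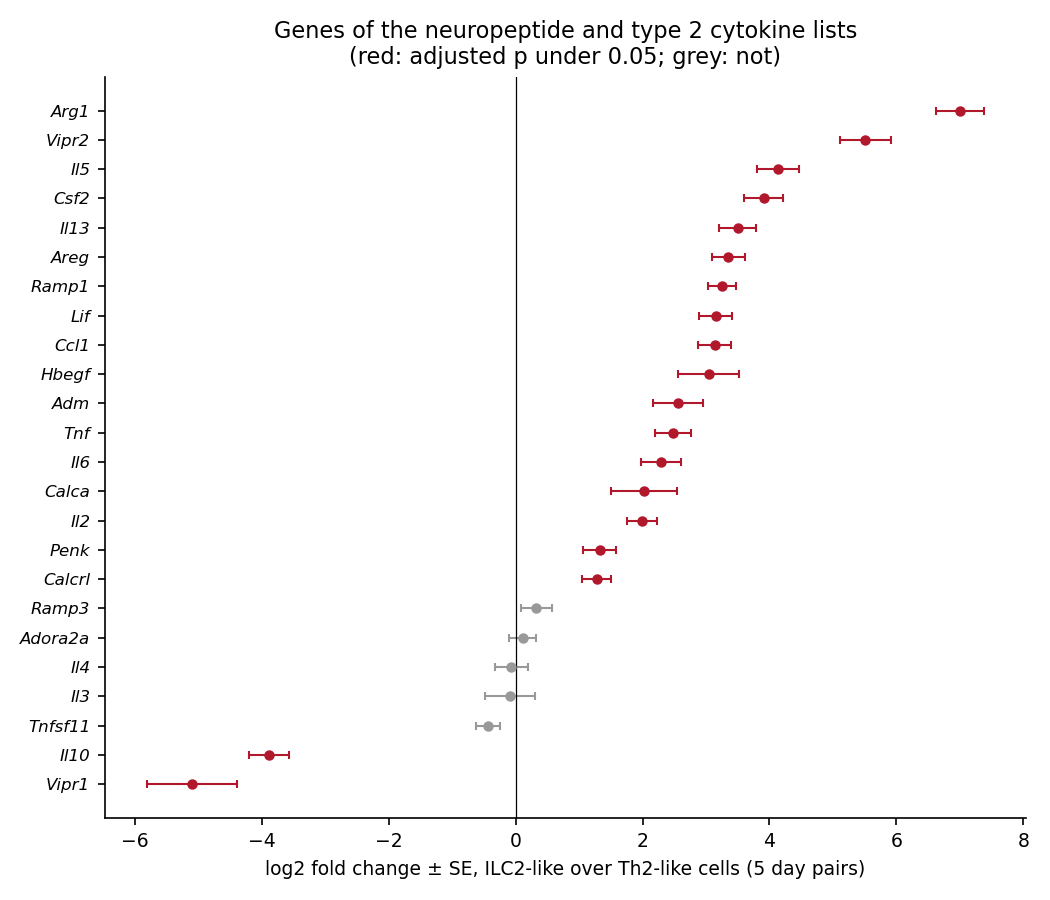
Log2 fold change (± SE derived from the test, over 5 days) of tested left-out genes between ILC2-like and Th2-like cells, with red points past the threshold and grey points not. Arg1 stood farthest to the right at 7.0, Ramp3 at 0.33 and Vipr1 farthest to the left at -5.10. Il9 is not drawn, since it had 0 UMIs in Th2-like cells.

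Among the genes named by rank, Rgs18 (at least 87.7-fold), Bmp2 (119-fold), Runx1t1 (35.7-fold), Thsd4 (33.0-fold), Eng (18.2-fold), Nbea (15-fold) and Asic3 (13.2-fold) had 0 UMIs in Th2-like cells. Il9 was at least 375-fold higher, again through the 2 cells of day 5. Stab2, a scavenger receptor gene, had 4545 UMIs against 2, a ratio of 483 (134 to 3990), and Stxbp6 2425 against 1, a ratio of 516 (92.5 to 20400). Higher in Th2-like cells were T cell genes, Cd5 at -9.20, Cd40lg at -8.00, Cd3d at -7.93, Gramd3 at -7.69 and Cd6 at -7.64. Cd4, Dapl1, Ccl3 and Nsg2 had 1 to 3 UMIs in ILC2-like cells, with ratios of 2310 (788 to 11200), 715 (196 to 5930), 127 (41.9 to 628) and 555 (97.7 to 22100). Galnt9 had 0, at least 79.9-fold lower.

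Several lists separated the classes. Interferon response genes were lower in ILC2-like cells in 11 of 13 and higher in 0 (list alone 11 and 0), with Isg15 at -1.01 ± 0.23. Cytotoxic and type 1 genes were lower in 10 of 12 and higher in 0 (list alone 10 and 0), with Ifng at -5.63 ± 0.49. Gzma, Gzmb and Nkg7 were among the 10. They stood at 3590, 131 and 874 CPM in ILC clusters 5 and 12 at day 5, against 27.1, 4.06 and 22.6 in ILC2-like cells. Those clusters are not in the ILC2-like class, so the result for these 3 genes holds for the class as named. CD3 and other sort-gate genes were lower in 8 of 9 (list alone 8). Early response and dissociation stress genes were higher in 12 of 18 and lower in 2 (list alone 13 and 2), with Fos at 1.67 ± 0.20. Of the cAMP response genes, 8 of 14 were higher and 2 lower (list alone 9 and 2), with Nr4a3 at 1.47 ± 0.21. The alarmin receptor list, part of which named both classes, was higher in 13 of 19 (list alone 13). Type 3 genes were higher in 4 and lower in 1 of 6 (list alone 4 and 2), with Tmem176b at 5.36 ± 0.29. Lipid handling genes were higher in 3 of 12 (list alone 3), glycolysis genes in 3 and lower in 1 of 14 (list alone 4 and 1), and cell cycle genes in 2 and lower in 1 of 20 (list alone 2 and 1). Trafficking genes split 7 to 7 of 16 (list alone 7 and 7), with Cd69 at 2.05 ± 0.21 and S1pr1 at -4.26 ± 0.25. Checkpoint genes split 4 to 4 of 13 (list alone 4 and 5), and regulatory T cell genes 4 to 5 of 12 (list alone 4 and 5).

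Of 10200 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 1591 were higher in ILC2-like and 1210 in Th2-like cells. Th2-like sums of steady state, day 2 and day 5 held 86, 84 and 37 cells. The counts were 935 and 468 without the day 14 pair, 1047 and 561 without the day 9 pair, 876 and 631 with the DESeq2 Wald test, and 899 and 545 without the block. Calca missed the threshold with the DESeq2 Wald test (adjusted p = 0.401) and with limma-voom (0.115), against a range of 3.43e-19 to 0.401 over 19 alternatives. Penk missed it in 6 of 19 alternatives (range 3.82e-06 to 0.625), Il6 and Il9 without the block (0.259 and 0.0519; ranges 8.21e-21 to 0.259 and 3.93e-20 to 0.0519), Galnt9 with the DESeq2 Wald test (0.0717; range 4.03e-18 to 0.0717), and Asic3 with that test and limma-voom (range 1.05e-17 to 0.715).

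Over the time course, the question was how CGRP, its receptor genes and type 2 effectors stood in ILC2-like cells as infection went on. Calca was at 1710 CPM at steady state, 10210 at day 2, 920 at day 5, 734 at day 9 and 694 at day 14. The log2 ratio to steady state was 2.57 at day 2 (ratio interval 5.81 to 6.15) and -0.89, -1.21 and -1.29 at days 5, 9 and 14. Il5 was also highest at day 2, at 3229 CPM against 1842 at steady state, and stood at 2739, 966 and 1236 at days 5, 9 and 14. Il13 took another course, at 739, 520, 1289, 1907 and 1580 CPM. Ramp1 stood at 493 CPM at steady state, 569 at day 2, 694 at day 5, 661 at day 9 and 547.5 at day 14. The ILC2-like class held different clusters over time, and these levels were not adjusted for that. Cluster 4, in which Calca was the leading gene although kept out of the clustering, held 1081 of 2236 ILC2-like cells at day 2 and 6 of 1437 at steady state, where cluster 3 held 585 and cluster 1 390. Cluster 14, with medians of 838 UMIs and 8.31% mitochondrial UMIs, held 156 ILC2-like cells at steady state and 5 at day 2. Cluster 0 held 1215 of 2204 at day 9 and 1598 of 3635 at day 14.

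At day 2, 88.6% of ILC2-like cells (median 3829 UMIs) had a Calca UMI, against 50.6% at steady state (median 1800 UMIs). With cells thinned to 700 UMIs the shares were 38.1%, 64.0%, 26.2%, 22.3% and 21.0% from steady state to day 14, with 74 shallower steady-state cells left out. Endothelial-like cells, which should lack the gene, had a Calca UMI in 3.60% at steady state (median 1425 UMIs) and 61.2% at day 2 (median 2530 UMIs, thinned 29.1%). Their Calca level was 46.9 CPM at steady state and 3720 CPM at day 2. The class lay in different clusters, with 732 of 834 cells in cluster 8 at steady state and 228 of 237 in cluster 10 at day 2. The ILC2 marker scores of these clusters were -1.03 and 0.05. The day 2 share of cells with a UMI may thus hold a background, which was not separated from doublets or a different kind of cell in cluster 10. At day 2 there were 13.1 Calca UMIs per endothelial-like cell and 4.62 per NK or ILC1-like cell (median 2959 UMIs).

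Ramp3 was at 1108 CPM at steady state, 1463 at day 2, and 635, 542 and 765 at days 5, 9 and 14. Adm was at 14.3, 60.9, 34.9, 5.98 and 4.97 CPM, and Penk, the enkephalin precursor gene, at 3.15, 17.7, 17.9, 27.1 and 17.9. Few cells carried Penk, with UMIs in 30 of 2236 cells at day 2, where 99 of 182 UMIs lay in 2 cells, and in 40, 54 and 51 cells at days 5, 9 and 14. Adora2a was called lower at days 2 and 9 (-0.78 and -0.87). Calcrl stood at 27.6, 17.3, 29.7, 31.9 and 37.2 CPM, and Vipr2 at 16.1, 24.4, 14.9, 23.2 and 28.0. Calcb, Ramp2, Nmur1, Vipr1, Calcr, Vip and Tacr1 were under 3 CPM at each time. Of 12 measured genes of the neuropeptide list, 3 were called higher and 2 lower at day 2, 2 and 3 at day 5, 1 and 5 at day 9, and 2 and 3 at day 14.

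Several cytokine genes were lower at day 2 than at steady state. Il2 was at 457 CPM at steady state and 24.8 at day 2, and at 169, 59.2 and 90.1 later. Ccl1 was at 3801 and 652 CPM at steady state and day 2, Csf2 at 2089 and 1026, Lif at 104 and 18.7, and Il4 at 39.2 and 6.82, where 47 of the 112 steady-state Il4 UMIs lay in 2 cells. Il3 was at 15.04 and 2.05. Tnf was called lower at days 5 and 9, at 29.2 and 16.9 CPM against 50.0 at steady state. Later, Arg1 was at 751 CPM at day 5 and 1031 at day 9 against 389 at steady state. Il6 was at 119 and 88.1 CPM at days 9 and 14 against 20.3, Tnfsf11 between 73.4 and 221, and Areg between 1960 and 3341. Il10 was at most 5.47 CPM and Hbegf at most 10.5. Il9 was at 509 CPM at day 5 and between 3.42 and 6.53 at the other times. Of the 5138 day 5 UMIs of Il9, 2891 lay in 1 cell, and 81 of 1914 cells had any. Of 16 type 2 effectors, 1 was called higher and 8 lower at day 2, 3 and 5 at day 5, 4 and 7 at day 9, and 3 and 5 at day 14.

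**Figure D3:**
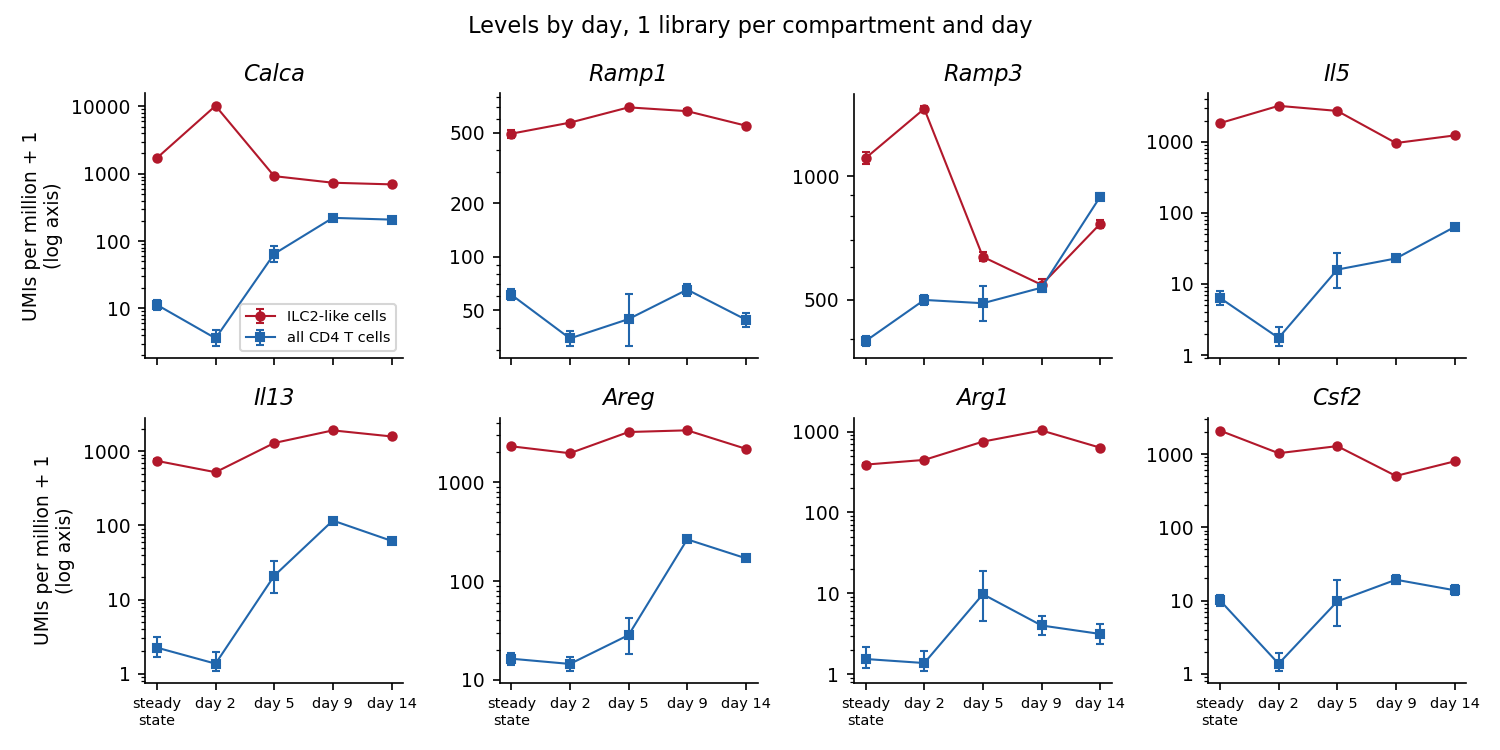
CPM plus 1 (log axis) of 8 genes by time in ILC2-like cells (red circles) and all CD4 T cells (blue squares), with exact Poisson 95% intervals and 1 library per point. Calca in ILC2-like cells stood at 10210 CPM at day 2 and 694 at day 14, while in CD4 T cells it stood at 10.3 CPM at steady state and 207 at day 14.

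Beyond these lists, day 2 ILC2-like cells stood higher than steady state in Tgm2 (4.74-fold on the CPM plus 5 scale), Aqp3 (4.27), Hhex (4.17) and Rhob (3.96). At day 5, the proliferation-linked genes Stmn1 (7.23-fold) and Cks1b (4.37) were higher, with Tnfrsf4, which encodes the costimulatory receptor OX40 (6.57), Il1r2, a decoy receptor gene for IL-1 (5.66), Lilrb4a (4.25), Ly6a (4.22), Igfbp7 (3.96), Ccr7 (3.69) and Tph1, the serotonin synthesis enzyme gene (3.54). Lower at day 5 were Itgb3 (6.00-fold), Large (4.85), Gdap10 (4.67), Arl5b (4.14), Crim1 (3.91) and Neurl3 (3.79). Il1r2 was at 2.80 CPM at steady state, 395 at day 9 and 156 at day 14. Tnfrsf4 was 16.9-fold and 8.72-fold higher at days 9 and 14, and Itgae 11.3-fold and 9.68-fold. Ctla4 was 15.5-fold higher at day 9, and Plac8 and Il17a 10.3-fold and 8.43-fold at day 14. Il17a was found in 129 of 3635 cells at day 14, and 76.0% of its 757 UMIs lay in 36 cells. Tff1 had 0 UMIs at steady state and was at 53.6 CPM at day 9. Cxcl1 was 16.4-fold and 31.8-fold lower at days 9 and 14, and Ccl21a, a gene of lymphatic endothelium, 17.1-fold and 9.90-fold lower, in a steady-state library with 33.8% endothelial-like cells. The rule also named Sftpc, Sftpa1, Sftpb and Lyz2 as lower than at steady state, but 1970 of 1973 Sftpc, 276 of 276 Sftpa1, 149 of 149 Sftpb and 175 of 177 Lyz2 UMIs at steady state lay in 2 cells.

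By list, cell cycle genes had the most members called higher in ILC2-like cells at day 5, with 16 of 20 called higher and 0 lower and a median log2 ratio of 1.17, although the cycling cluster is not in this class. At day 9 the counts were 12 and 1 (median 0.69), at day 14 4 and 1, and at day 2 1 and 1. Interferon response genes followed, with 8 of 12 called higher at day 5 (median 0.74), 10 at day 9 (0.83), 3 at day 14 and 0 at day 2, and 1 called lower at day 14. Of 14 glycolysis genes, 5, 5, 3 and 1 were called higher at days 2, 5, 9 and 14, and 1, 1, 1 and 2 lower, with a median of 0.49 at day 2. Cytotoxic and type 1 genes were called higher in 4 of 10 at day 5 and 4 at day 9. At day 2 they were called lower in 1, and at day 14 higher in 2. Of 19 alarmin receptor and identity genes, 8, 5, 5 and 4 were called lower at days 2, 5, 9 and 14 and 1, 1, 3 and 1 higher. Of 14 cAMP response genes, 5, 5, 4 and 5 were called lower and 3, 0, 3 and 4 higher, with a median of -0.44 at day 5. Its day 14 median was -0.02, and 0.03 after TMM scaling.

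The other lists gave mixed counts in ILC2-like cells. Early response and dissociation stress genes had 4, 3, 1 and 1 called higher and 2, 4, 6 and 3 lower of 19 at days 2, 5, 9 and 14. Trafficking genes had 3, 3, 2 and 3 higher and 4, 3, 4 and 4 lower of 15. Checkpoint genes had 2, 3, 4 and 2 higher and 3, 2, 3 and 4 lower of 14, and their day 5 median was -0.03, or 0.08 after TMM scaling. Regulatory T cell genes, which include Tnfrsf4 and Ctla4, had 5, 3, 4 and 4 higher and 2, 2, 1 and 2 lower of 10. Lipid handling genes had 0, 1, 3 and 1 higher and 2, 1, 1 and 1 lower of 14. Type 3 genes had 0, 1, 3 and 2 higher and 3, 0, 2 and 2 lower of 8, with a median of -0.49 at day 2 and, at day 5, -0.03 or 0.04 after TMM scaling. CD3 and other sort-gate genes had 0, 0, 1 and 1 higher and 1, 0, 0 and 1 lower of 7.

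**Figure D4:**
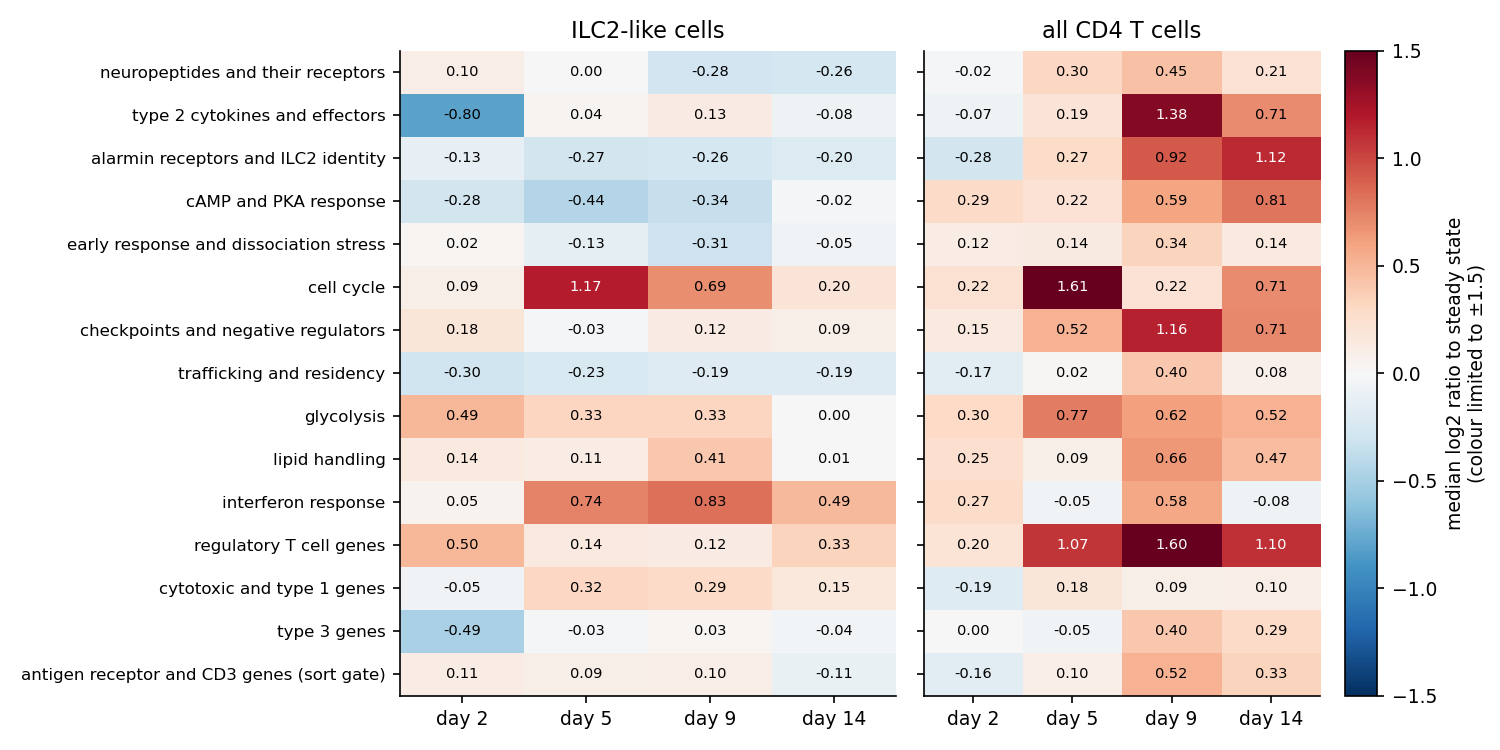
Median log2 ratio to steady state of the 15 gene lists at days 2, 5, 9 and 14 in ILC2-like cells (left) and all CD4 T cells (right), red for higher and blue for lower, with 1 library per day. Cell cycle genes stood at 1.17 in ILC2-like cells and 1.61 in CD4 T cells at day 5. In CD4 T cells at day 5, the medians of the early response, trafficking, lipid handling and sort-gate lists change sign after TMM scaling, as do those of the cAMP list at day 14 and of the checkpoint and type 3 lists at day 5 in ILC2-like cells.

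These day-to-day values in ILC2-like cells carry counting error only, and a difference between single libraries cannot be told from a difference between days. Arg1 at day 5 had a log2 ratio of 0.94, and of -0.01 with 3 further ILC clusters, drawn mostly from days 5 and 9, in the class, and likewise Ramp1 moved from 0.49 to -0.65, Il5 from 0.57 to -0.38 and Areg from 0.48 to -0.38.

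In CD4 T cells the same questions were asked, and most measured type 2 effectors stood higher at days 9 and 14 than at steady state. Calca was at 10.3 CPM at steady state, 2.59 at day 2, 63.6 at day 5, 220 at day 9 and 207 at day 14, with log2 ratios of -1.01, 2.16, 3.88 and 3.79. Il13 was at 1.25 CPM at steady state and 115 at day 9, Il4 at 1.43 and 41.0, and Areg at 15.4 and 263. Il5 was at 5.37 CPM at steady state, 21.9 at day 9 and 62.5 at day 14. Ramp3 was at 395 CPM at steady state and 891 at day 14, while Ramp1 stayed between 33.7 and 64.4.

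Calca in CD4 T cells lay mainly in the Th2-like class. At day 9, 30.1% of Th2-like cells (median 2966 UMIs) and 1.37% of naive-like cells (median 2647.5 UMIs) had a Calca UMI, at 633 and 5.53 CPM. At day 14 the shares were 34.1% (median 2978 UMIs) and 2.49% (median 2638 UMIs), at 451 and 9.16 CPM. At steady state Th2-like cells were at 343 CPM, with a UMI in 13 of 86 cells. At day 2, 0 of 84 Th2-like cells (median 2843 UMIs) had one, most of them from another cluster than at days 9 and 14.

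Of 9 measured neuropeptide genes, 0 were called higher and 2 lower at day 2, and 4, 3 and 4 higher and 0 lower at days 5, 9 and 14. Penk and Adora2a were called higher at days 5, 9 and 14, with log2 ratios of 1.10, 1.13 and 0.94 and of 0.80, 0.98 and 1.25. Calcrl and Vipr1 stood between 3.74 and 13.5 CPM, and Adm, Calcb, Nmur1, Vipr2, Ramp2 and Tacr1 at 3.74 CPM or less. Of 15 measured type 2 effectors, 9 were called higher at day 9 and 10 at day 14, with 0 lower and medians of 1.38 and 0.71. At day 5, 6 were called higher, and at day 2, 3 were called lower. Tnfsf11 was at 19.2 CPM at steady state and 168 at day 9, Ccl1 at 11.4 and 73.3, Il10 at 0.806 and 31.1, Il6 at 0.358 and 18.7, and Csf2 at 9.04 and 18.2. At steady state, 84 of the 101 Csf2 UMIs lay in 1 cell and 121 of the 127 Ccl1 UMIs in 2 cells. Il2 stood between 7.97 and 21.2 CPM, and Il3, Lif, Tnf, Arg1, Hbegf and Il9 stood at 8.73 CPM or less at each time.

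Beyond these lists, the day 9 CD4 T library stood higher than steady state in Plac8 (32.6-fold on the CPM plus 5 scale), Il1rl1 (21.0), the interferon-induced genes Ifitm2 (14.2) and Ifitm3 (13.4), the residency-linked chemokine receptor gene Cxcr6 (12.3), Igfbp7 (11.5) and Hilpda (11.2). Plac8, Il1rl1 and Igfbp7 are markers that named the Th2-like class. Lower at day 9 were Ppp1r21 (3.14-fold), Acot2 (3.01), Plaur (2.96), Pik3ip1 (2.86), Txnip (2.71), Cnn3 (2.53), Fam101b (2.46), Txk (2.45), Mfhas1 (2.42) and Epb41 (2.36). Day 14 had Il1rl1 (20.9-fold), Plac8 (16.1) and Bcl2a1d (10.9) higher, with Il13 (10.5), and Trim25 (6.06-fold), Gdap10 (4.2), Klhl21 (3.96), Pik3ip1 (3.87) and Rcbtb1 (3.82) lower. Day 2 had the death receptor gene Fas (4.31-fold), Cdkn1a (3.40), Abtb2 (3.29), Ctsl (2.88) and Rgs1 (2.81) higher, and Itgb3 (4.67-fold), Trim25 (4.50), Gdap10 (4.21), Madd (3.78) and Arf3 (3.72) lower. Day 5 had S100a6 (8.64-fold), Lgals7 (6.73), Anxa2 (6.12), Cd74 (6.00) and Mt1 (5.64) higher and Trim25 (5.68-fold), Pik3c2a (4.64) and Madd (4.56) lower. Fam160b2 and Gdap10 were also named at day 5, with 2 and 3 UMIs in that library. Itgb3 and Gdap10 were among the named lower genes of ILC2-like cells at day 5 as well.

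Most lists had more members called higher than lower in CD4 T cells after day 2. Regulatory T cell genes had 9 of 12 called higher at day 5, 9 at day 9 (median 1.60), 8 at day 14 and 2 at day 2, with 0 lower. Checkpoint genes had 3, 5, 9 and 8 of 14 higher and 1, 0, 1 and 0 lower at days 2, 5, 9 and 14. Alarmin receptor and identity genes had 0, 6, 11 and 12 of 19 higher and 2, 2, 1 and 1 lower. Cell cycle genes had 2, 18, 1 and 13 of 20 higher and 0 lower, with a median of 1.61 at day 5. Glycolysis genes had 3, 10, 7 and 6 of 14 higher and 1 lower at day 2. Of the cAMP response genes, 4, 4, 7 and 8 of 14 were called higher and 1, 2, 1 and 1 lower. Lipid handling genes had 2, 3, 6 and 5 of 11 higher and 0 lower. Interferon response genes had 6, 2, 7 and 2 of 14 higher and 1 lower at day 14.

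Early response and dissociation stress genes had 4, 1, 7 and 5 of 19 called higher in CD4 T cells and 1, 1, 2 and 1 lower. Trafficking genes had 2, 2, 6 and 4 of 16 higher and 2, 0, 2 and 1 lower. Cytotoxic and type 1 genes had 2, 5, 1 and 3 of 14 higher and 4, 1, 2 and 1 lower. Type 3 genes had 0, 1, 3 and 2 of 9 higher and 0 lower, and sort-gate genes 0, 0, 4 and 1 of 9 higher with 2 lower at day 2. After TMM scaling the median log2 ratio of all genes changed from 0.04 to -0.08 at day 5 and from 0.06 to -0.05 at day 9. In the small day 5 library, the list medians of early response (0.14 and -0.05), trafficking (0.02 and -0.09), lipid handling (0.09 and -0.04) and sort-gate genes (0.10 and -0.08) changed sign with that scaling.

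The CD4 T values also rest on 1 library per day. In the day 5 library of 224 cells, Il5, Il13 and Areg had log2 ratios of 0.94, 2.00 and 0.67, and of -0.86, -0.17 and -0.46 with cells of at least 500 genes.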

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

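The 3 patterns weighed below, and the tests of technical explanations for them, were chosen only after results were seen, except the neuroendocrine marker test, which was written before.

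The results given here drew attention as differences between groups, because the change from steady state went 1 way in the ILC2-like cells and the opposite way in the CD4 T cells. These differences were not tested, since each group had 1 library per day and no replicates. Log2 ratios are given for ILC2-like and then CD4 T cells. Calca stood at 2.575 and -1.010 at day 2, at -0.891 and 2.165 at day 5, at -1.214 and 3.879 at day 9, and at -1.295 and 3.794 at day 14. Il5 stood at 0.808 and -0.853 at day 2 and at -0.927 and 1.376 at day 9. Il2 stood at -1.408 and 1.014 at day 5 and at -2.280 and 0.655 at day 14. Ccl1 stood at -1.576 and 2.257 at day 9 and at -2.006 and 2.622 at day 14. Csf2 stood at -2.048 and 0.727 and Adora2a at -0.874 and 0.985 at day 9, and Il3 at -0.838 and 0.706 at day 14. In the CD4 T cells at steady state, 84 of 101 Csf2 UMIs lay in 1 cell and 121 of 127 Ccl1 UMIs in 2, which raised those levels and so lowered these CD4 T ratios. The CD4 T cells were taken whole, and their Th2-like share was 1.54% at steady state and 31.0% and 37.4% at days 9 and 14. Within Th2-like cells Calca stood at 343, 633 and 451 CPM at these times. No group had 4 to 10 samples of 1 condition, so no check for a sample far from the others was made.

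Calca was higher in ILC2-like cells at day 2 than at steady state. RNA free in the suspension was tested through endothelial-like cells, which held 13.1 Calca UMIs per cell (upper limit 13.5) at day 2, the most outside the ILC2-like class (4.62 in NK or ILC1-like cells), against a rise of 43.5 per ILC2-like cell, so free RNA may account for a part but not for the whole. With each cell thinned to 700 UMIs the log2 ratio was 2.546 (ratio interval 5.58 to 6.14). CPM is already divided by total UMIs, so thinning could hardly move this ratio, which cannot decide on sequencing depth. The share of cells with a Calca UMI does depend on depth. After thinning it was still higher at day 2 than at steady state, as given with the time course. Neuroendocrine epithelial markers came to 0.226% of the 104840 Calca UMIs (upper limit 0.257%), under the 5% set for such cells, and 203 of their 237 UMIs were Pcsk1. A response of ILC2-like cells to infection remains a hypothesis, since an effect of the single day 2 library could not be tested within the single-cell libraries. The labels also list separate RNA samples of lung ILC2s at steady state and day 2, which were not analysed here.

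Gzma and Nkg7 were high in 2 ILC clusters, numbers 5 and 12, drawn nearly all from day 5, and both genes were among those the clusters were formed from. Doublets of ILC2-like with NK or ILC1-like cells would bring the other NK markers. For each marker, the excess over ILC2-like cells in the 2 clusters was divided by that excess in NK or ILC1-like cells. The median of this fraction over 9 other NK markers was 0.00235 (upper quartile 0.00833), against 0.852 for Nkg7 and 21.7 for Gzma, with Gzmb as the exception at 0.932. Free RNA was tested through ILC2-like cells of the library, which held 0.143 Gzma UMIs per cell (upper limit 0.161) against 34.8, and T cells through CD3 genes, which stood at 30.4 CPM (upper limit 33.6) against 1450 in cluster 13, an unnamed cluster led by CD3 genes. In ILC2-like cells of day 5 the CD3 genes stood at 178 CPM, above clusters 5 and 12. A state of ILC2-like cells peculiar to day 5 may be a candidate explanation, as a hypothesis. An effect of that single library could not be tested within the single-cell libraries, and the separate RNA sample of day 5 lung ILC2s was not analysed here.

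Calca was found in Th2-like cells at days 9 and 14, at 74.1% of its ILC2-like level. ILC2-like cells or their RNA would bring Arg1, which stood at 0.664% of its ILC2-like level (upper limit 0.891%). Free RNA was tested through naive-like cells, which held 0.0204 Calca UMIs per cell (upper limit 0.0263, median 2645 UMIs) against 1.91 in Th2-like cells (median 2969 UMIs). Expression by the Th2-like cells themselves may explain it, as a hypothesis, with library effects untested.

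Other splits of the 10 sums into 5 and 5 were counted, with 100 drawn, the real one included. Between ILC and CD4 T libraries, 1 of 100 splits, the real one, gave as many genes (5870, highest other 6). For left-out genes between ILC2-like and other cells it was also 1 of 100 (19, highest other 1), and between ILC2-like and Th2-like cells 1 of 100 (2801, highest other 1465). Most of these splits put both sums of some day on the same side, whereas the fit holds day as a block. Of the splits that parted all 5 days, 12 were drawn, the real one included, too few for a share under 0.05. Their highest other counts were 1, 0 and 1300.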

How the results depend on the processing

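Added only after results were seen were the removal of top doublet scores, the libraries without endothelial-like, stromal-like and B-like cells, and the moves of clusters 5, 10, 11 and 12. The single values that stand for the untested results (Calca at days 2 and 9, the ILC2-like share at day 9) were also chosen then. The tested comparisons held day as a block, and their counts with no block are given below. For the values between days, no paired analysis was possible because they come from no test, with 1 library per group and day. Among genes in tests, 1415 values kept their side of the threshold, 28 gained and 70 lost it, and 0 values of genes past it in the main test reversed direction. With pairs left out in turn the numbers were 575, 4, 19 and 0. A change of direction in a gene that missed the threshold in the main test was not counted as reversed. Among genes between 2 days, 2236 values moved less than their interval, 761 more, and 19 called ones reversed. The cause was not tested for any value below, except where fewer cells enter by construction. Depth limits genes of low level, such as Nmur1 and Calcb.

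Genes higher in ILC and in CD4 T libraries numbered 1414 and 1016 with libraries subsampled to the smallest, 2453 and 1768 with no block, and from 2432 to 3333 and from 1699 to 2254 with pairs left out in turn. Left-out genes higher in ILC2-like than other cells numbered 10 with no block, 9 with doublet calls kept, 9 at the 5% mitochondrial limit, 7 with at least 500 genes per cell, 10 with top doublet scores removed and 7 at resolution 1.2, and from 10 to 17 with pairs left out. Lower ones numbered 1 with no block and 1 with top doublet scores removed, and from 1 to 2 with pairs left out. Genes higher in ILC2-like and in Th2-like cells numbered 876 and 631 with the DESeq2 Wald test, 899 and 545 with no block, and from 935 to 1620 and from 468 to 1329 with pairs left out.

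Calca in ILC2-like cells at day 2, 2.575, was 2.621 with TMM, 2.694 at the 5% mitochondrial limit and 2.822 with at least 500 genes. Calca in CD4 T cells at day 9, 3.879, was 4.291 and 2.986 with pseudocounts of 1 and 20 CPM. The ILC2-like share at day 9, 82.8%, was 94.252% and 43.576% at resolutions 0.4 and 1.2, 79.677% with all variable genes, 42.186% with doublet calls kept, 54.380% at the 5% mitochondrial limit, 43.781% with at least 500 genes, 50.251% with top doublet scores removed and 95.455% with clusters 5, 11 and 12 in the class.

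Reversed log2 ratios in ILC2-like cells were, with all variable genes, doublet calls kept, the 5% mitochondrial limit and top doublet scores removed, for Sftpb 0.160, 0.162, 0.113 and 0.164 at day 2 and 0.057, 0.089, 0.030 and 0.061 at day 5, and for Lyz2 0.774, 0.679, 0.766 and 0.716 at day 5. Sftpc at day 5 was 0.005 with doublet calls kept and 0.006 with top doublet scores removed, and Arg1 at day 5 -0.010 with clusters 5, 11 and 12. In CD4 T cells at day 5, Penk was -0.084 after thinning, and Areg, Il13 and Il5 were -0.460, -0.166 and -0.859 with at least 500 genes.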

Other observations

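The cells described in this part were chosen only after results were seen, and their levels were not tested.

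At day 5 the ILC library held 1325 cells in clusters 5 and 12 (median 8975 UMIs) beside 1914 ILC2-like cells (median 4341 UMIs). The 2 groups differed in genes that had not formed the clusters. Il13 stood alike, at 1320 CPM in the clusters and 1290 in ILC2-like cells, while Il5 stood at 373 and 2740, Arg1 at 103 and 751, and Areg at 648 and 3210. Ramp1 stood at 14.2 against 694 CPM and Calca at 276 against 920. Il4 stood at 92.8 against 29.2 CPM, and Il10 at 30.1 against 0.892. Among genes open to the clustering were Klrg1 at 669 against 169 CPM, the gut-homing receptor gene Ccr9 at 435 against 7.44, and S1pr1, whose product guides cells out of tissue, at 61.6 against 3.17.

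Cluster 11 of the ILC libraries held 303 cells at day 9 and 183 at day 14. At day 9 its Il13 stood at 1830 CPM, Areg at 3080 and Ramp1 at 423, against 1910, 3340 and 661 in ILC2-like cells, and Calca at 344 against 734. The antigen presentation genes Cd74 and H2-Aa stood at 5040 and 1090 CPM against 499 and 40.3, and were open to the clustering. With clusters 5, 11 and 12 added, the ILC2-like share at day 9 was 95.455%.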
